A study of Homo sapiens with 12 samples.

How the data were processed

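Gene expression was measured in MCF7, an established luminal breast cancer cell line, on 12 Affymetrix whole-transcript arrays. Per the labels, MCF7 cells carried either a Neo selection gene alone (control cells) or the thyroid hormone receptor TRβ (TRβ cells). Cells of both lines were analysed without added hormone and with 25 nM triiodothyronine (T3), the active thyroid hormone. This gave 4 groups of 3 arrays. The duration of the T3 treatment is not given in the sources used here. Per the labels' protocols, total RNA was converted to biotin-labelled single-stranded cDNA, and the cells grew in medium with fetal bovine serum.

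The authors deposited 1 table of log2 values for 67528 probe sets on each of the 12 arrays. Per the submitters' processing notes, these values were made with RMA in Transcriptome Analysis Console 4.0. RMA corrects the background, normalizes the arrays to each other and summarises the probes of each probe set, so an overall difference in RNA amount between groups is no longer visible in the values. The genome build of the array annotation is not given in the sources used here, and no coordinates are reported. The array medians lay between 4.72 and 4.87. The table holds no detection call and no background level, so signal near the median of all probe sets was not separated from background. The number of arrays, 3 per group, limits the precision.

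Gene names came from the platform annotation. Of the probe sets, 23781 had 1 gene symbol, 1543 had several and 42204 had none in that table. Symbols were compared through gene identifiers with the RefSeq annotation of GRCh38.p14, which changed 0 of them. That annotation was otherwise used only for the order of neighbouring genes. Each of 22465 genes was represented by its probe set with the highest mean over all arrays. A probe set named for a microRNA was taken to read the precursor or host transcript under this protocol, which was not tested.

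Every probe set was tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) on the deposited log2 values, with 1 mean per group over all 12 arrays and 8 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all 67528 probe sets in each comparison, and an adjusted p under 0.05 was called. The comparisons were T3 in TRβ cells, T3 in control cells, TRβ against control cells without T3, the same with T3, and the difference between the T3 responses of the 2 lines. Fold changes are differences of mean log2 signal, given with the standard error (SE) of the fit. The labels do not say whether the replicates are separate cultures, so all p-values measure only the spread between these samples, which may be technical. They also do not say whether each line is a single clone or a pool. Any difference between TRβ and control cells, also in their T3 response, may therefore come from the lines and not from the receptor. No identical arrays were found: at most 2.99% of values coincided between any 2 arrays.

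Before the data were examined, 25 gene lists with 494 entries were written down, of which 444 entries matched a named probe set. Each list was tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 25 lists of a comparison. Camera with an estimated correlation and fry, which tests whether the members move on balance one way without comparing them with other genes, were run as alternatives. The genes named in the text follow a rule that was also fixed then. They are 9 genes of thyroid hormone and estrogen action and proliferation (THRB, THRA, KLF9, HR, THRSP, DIO1, ESR1, PGR and MKI67), up to 12 genes with the largest rise and 12 with the largest fall in each comparison among called genes whose groups did not overlap (10 and 10 for the difference of T3 responses, without that condition), and up to 4 members of each list with the largest moderated statistic. Genes outside this rule are said to have been chosen after their values were seen.

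Also fixed then were the alternatives: eBayes without the trend, robust eBayes, fits on only the 2 groups compared, the replicate number as a block, quantile normalization, centring of array medians, removal of dim probe sets, 1 probe set per gene, array weights, other thresholds and leaving out each array in turn. Removal of the 1462 probe sets on alternate haplotype sequences was added after the data were seen. The fit was tested on simulated log2 values in which 66 or 67 probe sets were changed at each of 3 sizes. The noise was drawn independently for each probe set and few probe sets were changed, unlike in the real data. The shares below are therefore not error rates of the real comparisons. For T3 in TRβ cells it called 38.8% of simulated changes of 0.5 (log2), 83.6% of those of 1 and 98.5% of those of 2, and 2% of its calls were false. For T3 in control cells it called 50.7%, 85.1% and 100% for the same sizes, with 4.27% false. Without T3, TRβ against control gave 49.3%, 94.0% and 100% with 6.36% false. With T3, it gave 53.7%, 85.1% and 98.5% with 7.06% false. The difference of T3 responses gave 14.9%, 70.1% and 95.5% with 2.44% false.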

Results

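The arrays compared MCF7 control cells with MCF7 cells that received the thyroid hormone receptor TRβ, each without and with 25 nM T3, with 3 arrays in each of the 4 groups. The series asks what this receptor does in breast cancer cells and names the self-renewal of their stem cells as its subject; these arrays come from adherent cultures. Arrays of the same group correlated at 0.991 to 0.996 over all 67528 probe sets, and the lowest correlation between any 2 arrays was 0.976. The first principal component, with 47.9% of the variance, set the 3 T3-treated TRβ arrays apart from the other 9. The second component, with 20%, had the untreated TRβ arrays at its lowest end.

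THRB, the gene that was introduced, was measured first. Its signal was 6.90 ± 0.16 (log2, SD, n = 6) in the TRβ arrays and 6.06 ± 0.04 (SD, n = 6) in the control arrays, a 1.79-fold difference with no overlap (exact two-sided permutation test over 924 splits, p = 0.00216). THRB was higher in TRβ cells by 0.72 ± 0.06 (log2, SE) without T3 and by 0.97 ± 0.06 with T3. THRA, which encodes the related receptor TRα, did not pass the test between the untreated lines (0.04 ± 0.07, adjusted p = 0.857). It was lower in TRβ cells with T3 (-0.24 ± 0.07, adjusted p = 0.0382). The settings that ended this call included leaving out T3-treated control replicate 1 (0.0971) or 3 (0.131). In TRβ cells THRA fell with T3 (-0.57 ± 0.07, adjusted p = 2.14e-04).

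**Figure D1:**
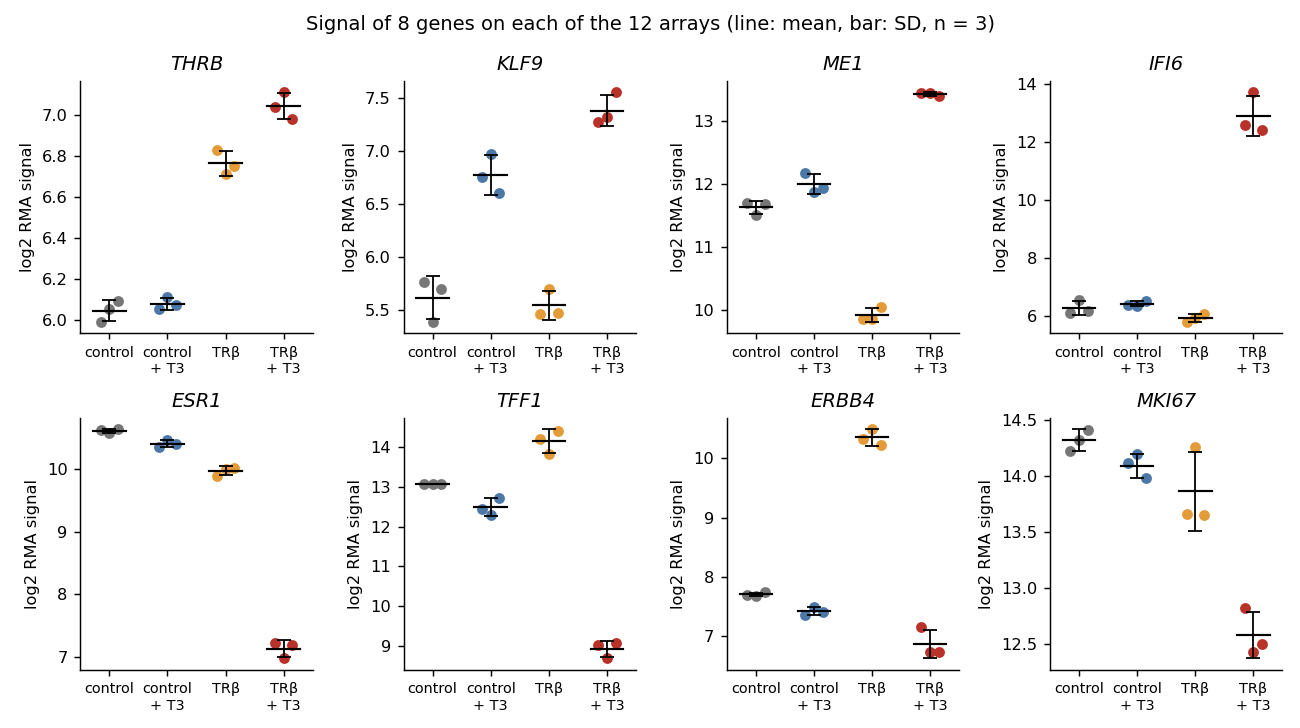
Log2 RMA signal (vertical axis) of 8 genes in the 4 groups (horizontal axis); points are single arrays, lines the mean and bars the SD of 3 arrays, and each panel has its own scale that does not start at 0. THRB is higher in both TRβ groups, IFI6 is high only on the 3 T3-treated TRβ arrays, and ESR1 and TFF1 are lowest there.

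The first comparison asked how T3 changed expression in cells carrying the added receptor. GLYATL2, a glycine acyltransferase gene, rose 261-fold (8.03 ± 0.18, log2 ± SE). IFI6, an interferon-induced gene, rose 127-fold (6.99 ± 0.27), GABRQ, a GABA receptor subunit gene, 68.4-fold (6.10 ± 0.11), and ALDH1A3, which encodes a retinal-oxidising aldehyde dehydrogenase, 50.8-fold (5.67 ± 0.11). ENPP2, which encodes autotaxin, rose 45.4-fold, HEG1 39.1-fold, UBD, a ubiquitin-like gene, 33.4-fold, IFIH1, a sensor of double-stranded RNA, 22.7-fold, and TNFSF10, the gene of the death ligand TRAIL, 21.5-fold. STC1, COLEC12 and the probe set named MIR21 rose by 4.48, 4.45 and 4.27 (log2). TFF1, an estrogen-induced secreted peptide gene, was 37.5-fold lower (-5.23 ± 0.16). GFRA1, a co-receptor gene of RET, was 32.7-fold lower, EFEMP1 17.8-fold, the anti-apoptotic gene BCL2 13.5-fold, the amino acid transporter gene SLC7A2 11.7-fold and the receptor tyrosine kinase gene ERBB4 11.1-fold. NEDD4L, NPNT, PRLR, DCPH1, RHOB and the glucose transporter gene SLC2A1 were 8.22- to 9.74-fold lower. ESR1, which encodes estrogen receptor α, was 7.14-fold lower (-2.84 ± 0.08), and the proliferation marker MKI67 2.42-fold lower (-1.27 ± 0.16).

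Among the classical thyroid hormone-responsive genes, KLF9 rose 3.57-fold in TRβ cells (1.84 ± 0.13, adjusted p = 1.81e-06) and ME1, which encodes malic enzyme, by 3.5 ± 0.10. HIF1A rose by 0.92, and TXNIP fell by 1.66. DIO1, a deiodinase gene induced by T3 in liver, and the estrogen-induced gene PGR did not pass (0.07 and -0.14, adjusted p = 0.491 and 0.251). HR rose by 0.29 ± 0.06 and THRB by 0.28 ± 0.06. THRSP, a lipogenic gene, was 0.38 ± 0.11 higher at an adjusted p of 0.0397, a call that ended with quantile normalization (0.0700), centring of array medians (0.0670) and array weights (0.102), and without TRβ replicate 2 (0.129), TRβ replicate 3 (0.101), T3-treated TRβ replicate 1 (0.121) or 2 (0.0976), untreated control replicate 2 (0.0542) or T3-treated control replicate 2 (0.0564). With only the 6 TRβ arrays in the fit, HR, THRB and THRSP did not pass (adjusted p = 0.0554, 0.0926 and 0.0909). Of the 27 T3-induced genes, 9 rose and 3 fell (10 and 4 adjusted over the list alone). The list was called higher at an adjusted p of 0.0462 (adjusted p = 0.138 with an estimated correlation).

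The interferon-stimulated genes rose most as a group: 16 of 20 measured members rose and none fell (19 rose adjusted over the list alone), with a median of 1.08 (log2). Besides IFI6 and IFIH1, RIGI rose by 2.95 ± 0.09 and OAS2 by 2.4 ± 0.10. Camera called the list at 6.12e-18 (adjusted p = 0.0527 with an estimated correlation). Camera did not call the markers of stromal, endothelial and immune cells in this comparison (adjusted p = 0.364), with a median of 0.05 over 16 members. Fry called these markers higher (adjusted p = 0.00472). One of them, the cadherin gene CDH5, rose by 2.43 ± 0.10.

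Of the 23 measured mitosis genes, 20 fell and none rose (21 fell adjusted over the list alone), with a median of -1.08. CDK1 fell by 1.40 ± 0.09, FOXM1 by 1.78 ± 0.12 and PLK1 by 1.65 ± 0.11. Of the 23 DNA replication genes, 20 fell and none rose (21 fell adjusted over the list alone), with a median of -0.90; CDC6 fell by 1.40 ± 0.09 and GINS1 by 1.01 ± 0.08. Both lists were called (adjusted p = 3.32e-16 and 9.07e-16), and neither with an estimated correlation (adjusted p = 0.134 for each). Of 30 estrogen-induced genes, 17 fell and 4 rose (19 and 5 adjusted over the list alone), with a median of -0.46. The carbonic anhydrase gene CA12 fell by 2.29 ± 0.12 and the co-chaperone gene FKBP4 fell by 1.28 ± 0.08, whereas NRIP1, which encodes a nuclear receptor corepressor, rose by 1.52 ± 0.09. Of 20 luminal epithelial markers, 11 fell and 1 rose (12 and 2 adjusted over the list alone). Beside ESR1, the transcription factor genes SPDEF and GATA3 fell by 2.41 ± 0.12 and 1.09 ± 0.09, and ELF3 rose by 1.23 ± 0.08. The estrogen and luminal lists were called at 7.58e-06 and 1.16e-04 (adjusted p = 0.178 and 0.138 with an estimated correlation).

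Stem cell-associated genes, the subject named by the series, moved both ways: 6 of 20 rose and 3 fell (6 and 4 adjusted over the list alone). Camera did not call the list (adjusted p = 0.641), whereas fry called it higher (adjusted p = 2.25e-05). ALDH1A3 and MYC rose (by 5.67 and 1.03 ± 0.09), while SALL4, a pluripotency factor gene, fell by 2.03 ± 0.10 and CD44, which encodes a hyaluronan receptor, by 0.73 ± 0.07. Of 18 cholesterol synthesis genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone); LSS fell by 0.92 ± 0.10 and INSIG1 rose by 0.73 ± 0.09. Of 17 p53 targets, 5 rose and 4 fell (9 and 4 adjusted over the list alone), among them GDF15 at 3.66 ± 0.28 and TP53INP1 at 1.83 ± 0.17. Of 14 immediate-early genes, 6 rose and 2 fell (6 and 3 adjusted over the list alone), with EGR1 at 2.21 ± 0.15 and KLF6 at 1.73 ± 0.14. These lists were called at adjusted p-values of 0.0287, 0.0364 and 0.0261 (adjusted p = 0.314, 0.228 and 0.234 with an estimated correlation). Each of these calls and that of the T3-induced genes rested on single arrays. Without T3-treated TRβ replicate 1 the p53, immediate-early and T3-induced lists had adjusted p = 0.105, 0.0629 and 0.0715. Without T3-treated TRβ replicate 3 the cholesterol and T3-induced lists had 0.0589 and 0.0523, without T3-treated TRβ replicate 2 or TRβ replicate 2 the T3-induced list had 0.0546 or 0.0909, and without TRβ replicate 1 the p53 list had 0.0515. With quantile normalization, the T3-induced and cholesterol lists had adjusted p = 0.102 and 0.119, and without dim probe sets these and the p53 list had 0.0997, 0.0997 and 0.0762. Neither camera setting called the other lists, including thyroid hormone signalling machinery (2 of 17 rose and 7 fell, 2 and 7 adjusted over the list alone) and mammary basal markers (5 of 12 rose and 1 fell, 5 and 1 adjusted over the list alone), at adjusted p = 0.169 and 0.0643.

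In total, limma called 9348 probe sets for T3 in TRβ cells, 4227 higher and 5121 lower. These represented 4817 of 22465 named genes, with 2187 higher and 2630 lower, of which 373 rose and 460 fell by at least 2-fold. The split of the probe sets was 4870 higher and 4792 lower after quantile normalization and 3715 and 5308 after centring of array medians, so which direction held more depended on the scaling. With only the 6 TRβ arrays in the fit, 6109 probe sets passed.

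The next comparison measured the response to T3 without the added receptor. In control cells T3 raised a short list of genes, and most of them also rose in TRβ cells. INSYN1 rose 5.03-fold (2.33 ± 0.19, log2 ± SE), COLEC12, a scavenger receptor gene, 3.98-fold (1.99 ± 0.15), STC1, which encodes the secreted glycoprotein stanniocalcin-1, 3.36-fold (1.75 ± 0.13), and INHBB, the inhibin βB subunit gene, 3.2-fold (1.68 ± 0.10). The metallothionein gene MT1X rose 3.17-fold, the sodium-calcium exchanger gene SLC24A3 2.24-fold and BCAS1 2.13-fold. KLF9 rose 2.23-fold (1.16 ± 0.13, adjusted p = 0.00777), a call that ended without T3-treated control replicate 2 (0.0532) and with only the 6 control arrays in the fit (0.0679). ESR1 differed by -0.21 ± 0.08 and MKI67 by -0.22 ± 0.16, and neither passed (adjusted p = 0.704 and 0.840). Of the mitosis genes, KIF11 differed by -0.30 ± 0.13 and did not pass. Camera called mitosis and DNA replication genes lower and oxidative phosphorylation genes higher (adjusted p = 3.72e-06, 1.59e-06 and 6.77e-05), with medians of -0.20, -0.15 and 0.09. These calls had adjusted p = 0.690 each with an estimated correlation, and no member passed over all genes (0, 1 and 1 members adjusted over the list alone). With fry their adjusted p-values were 0.254, 0.253 and 0.253.

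In control cells limma called 40 probe sets, 36 higher and 4 lower, or 28 genes higher and 2 lower, against 4488 probe sets at an unadjusted p under 0.05. Of these 30 genes, 29 moved in the same direction in TRβ cells and 28 were called there in that direction. The size of this list depended on single arrays. It was 13, 14 and 17 probe sets without untreated control replicate 1, 2 or 3, and 26, 11 and 13 without T3-treated control replicate 1, 2 or 3. Without T3-treated TRβ replicate 1 it was 67, and with array weights 89. Across all probe sets the T3 responses of the 2 lines, which share no arrays, correlated with Pearson's r of 0.302 and Spearman's rho of 0.126. These are correlations across probe sets, which are not independent replicates. Both lines called 33 probe sets higher, against 2.25 expected from independent lists, and 4 lower, against 0.303.

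**Figure D2:**
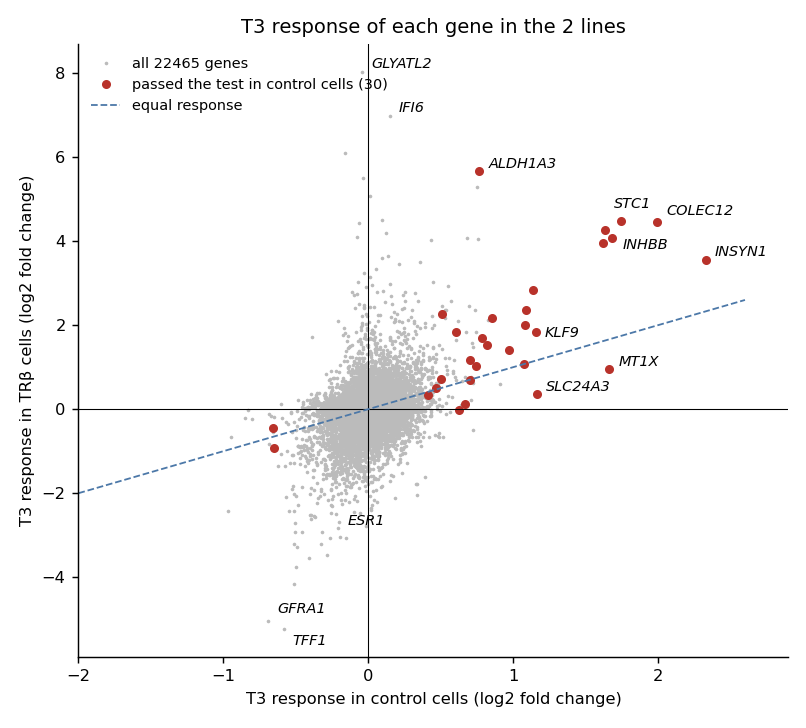
T3 response of each gene in control cells (horizontal axis) and in TRβ cells (vertical axis), both as log2 fold change between means of 3 arrays; red points are the 30 genes that passed the test in control cells and the dashed line marks equal responses. INSYN1 lies at 2.33 in control and 3.55 in TRβ cells, and SLC24A3 at 1.16 and 0.36.

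The difference between the responses of the 2 lines was tested directly. The T3 response was larger in TRβ than in control cells for STC1 (by 2.73), COLEC12 (by 2.45), INHBB (by 2.39) and INSYN1 (by 1.22). For SLC24A3 it was smaller, with a difference of -0.81, and for MT1X the difference of -0.72 did not pass (adjusted p = 0.0932). Among the 30 genes called in control cells, 16 responded more in TRβ cells and 11 did not pass the test of the difference. The response of ESR1 differed by -2.63 ± 0.12 and that of MKI67 by -1.05 ± 0.23. The difference for KLF9 was 0.68 ± 0.18 (adjusted p = 0.0472), and the settings that ended this call included centring of array medians (0.0745) and leaving out untreated control replicate 1 (0.105) or 3 (0.112), T3-treated control replicate 1 (0.106) or 3 (0.114), TRβ replicate 1 (0.110) or 3 (0.114), or T3-treated TRβ replicate 2 (0.0689) or 3 (0.102). Of the 20 interferon-stimulated genes, 16 had a larger response in TRβ cells (19 adjusted over the list alone), the 1 list that was called with both correlations (adjusted p = 2.81e-21, and adjusted p = 0.0313 with an estimated correlation). Mitosis and DNA replication genes had more negative responses for 16 and 15 of 23 members (20 and 19 adjusted over the list alone). Both lists were called (adjusted p = 7.17e-14 and 2.44e-13; adjusted p = 0.148 each with an estimated correlation). Estrogen-induced genes had more negative responses in TRβ cells for 13 of 30 members and more positive ones for 3 (18 and 4 adjusted over the list alone). Luminal markers had more negative responses for 9 of 20 and a more positive one for 1 (10 and 1 adjusted over the list alone), and cholesterol synthesis genes for 4 and 1 of 18 (7 and 1 adjusted over the list alone). These lists were called at 4.95e-06, 3.14e-06 and 0.0130 (adjusted p = 0.187, 0.144 and 0.284 with an estimated correlation), and the cholesterol call ended with quantile normalization (0.182) and without dim probe sets (0.0994). In total 4118 probe sets differed, 1838 with a higher and 2280 with a lower response in TRβ cells. After quantile normalization 2015 were higher and 1997 lower, and after centring of array medians 1441 and 2492, so which direction held more again depended on the scaling.

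Without T3, the comparison of TRβ with control cells shows the lines at baseline. It cannot separate the receptor from other differences between the lines. ERBB4, a receptor of neuregulins, was 6.25-fold higher in TRβ cells (2.64 ± 0.11, log2 ± SE). UPK1A, an urothelial plaque gene, was 3.83-fold higher, CACNG4, a calcium channel subunit gene, 3.69-fold, ZFP36L2, which encodes an mRNA decay factor, 3.44-fold and TM4SF1 3.27-fold. IL20, a cytokine gene, was 11.9-fold lower (-3.58 ± 0.16) and TFPI, the tissue factor pathway inhibitor gene, 9.58-fold lower (-3.26 ± 0.18). INHBB was 4.73-fold lower, STC1 4-fold and ME1 3.26-fold, and T3 raised these 3 genes in TRβ cells. MT2A and SMARCA1, also among the 12 genes with the largest fall, went down with T3 in TRβ cells (-1.08 and -0.45). Both comparisons use the untreated TRβ arrays, which by itself favours opposite directions, and no test was made of such a pattern for the lowest genes. ESR1 was 1.55-fold lower (-0.63 ± 0.08), while TFF1 was higher by 1.08 ± 0.16 and SALL4 by 1.16 ± 0.10. KLF9 differed by -0.07 ± 0.13 and did not pass (adjusted p = 0.833).

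Of 23 mitosis genes, 9 were lower and none higher in untreated TRβ cells (17 lower adjusted over the list alone), among them TTK at -1.05 ± 0.09 and AURKA at -0.75 ± 0.10. MKI67 differed by -0.46 ± 0.16 and did not pass (adjusted p = 0.119), but did without TRβ replicate 2 (-0.66, adjusted p = 0.0118). Of 23 DNA replication genes, 5 were lower (8 adjusted over the list alone), and of 18 cholesterol synthesis genes 5 were lower and 1 higher (8 and 1 adjusted over the list alone), with HMGCS1 at -0.52 ± 0.08 and MVD at -0.69 ± 0.11. These lists were called at 2.80e-08, 1.86e-04 and 0.00367 (adjusted p = 0.408, 0.442 and 0.408 with an estimated correlation). TGF-beta targets were higher for 5 of 13 members (6 adjusted over the list alone), with ID1 at 1.37 ± 0.17 and ID3 at 1.17 ± 0.15, and immediate-early genes for 3 of 14 (4 adjusted over the list alone), with EGR1 at 1.60 ± 0.15. Their adjusted p-values were 5.01e-04 and 0.0125 (adjusted p = 0.302 and 0.408 with an estimated correlation). Lipogenesis genes were lower for 4 of 15 members (5 adjusted over the list alone), among them ME1 and, at a smaller size, SCD at -0.62 ± 0.09. Heat shock genes were lower for 5 of 11 (7 adjusted over the list alone), among them HSPA4L at -0.95 ± 0.13, oxidative phosphorylation genes for 5 of 22 (9 adjusted over the list alone), among them NDUFB5 at -0.39 ± 0.07, and unfolded protein response genes for 4 of 16 (5 adjusted over the list alone). Of 30 estrogen-induced genes 8 were lower and 3 higher (9 and 5 adjusted over the list alone), with MYB at -0.94 ± 0.10. Camera called these 5 lists lower at adjusted p-values of 0.01 to 0.0176 (adjusted p = 0.442 each with an estimated correlation). Each of these 5 calls ended without dim probe sets (adjusted p = 0.0893, 0.0615, 0.0893, 0.0615 and 0.104, in the order named). The lipogenesis, oxidative phosphorylation and estrogen lists also had adjusted p = 0.0610 without TRβ replicate 2, and the estrogen list 0.0617 without untreated control replicate 3. With quantile normalization the estrogen, oxidative phosphorylation and heat shock lists had 0.0634, 0.0996 and 0.0871.

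Some of the strongly lower genes are neighbours, a feature chosen after the values were seen. Windows of 20 neighbouring expressed genes whose median difference between untreated TRβ and control cells was -0.5 or less formed 4 blocks, on chromosomes 1, 3, 6 and 20. The block on chromosome 1, from ATP1B1 to IL20, held 74 genes with a median of -0.62, and that on chromosome 20, from MAVS to MAPRE1, held 47 genes with a median of -0.61. The latter includes ESF1 (-2.23), SMIM26 (-1.77) and RBBP9 (-1.61), 3 of the 12 genes with the largest fall, and the replication gene GINS1 (-1.10). The blocks on chromosome 3, from MRPS25 to DYNC1LI1, and chromosome 6, from CRYBG1 to PERP, had medians of -0.48 over 22 genes and -0.56 over 53. Of the 196 genes in the 4 blocks, 137 were called lower without T3, against 1158 of all 6732 ordered genes. The blocks were chosen for low values in this same comparison, so their count is not independent evidence.

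**Figure D3:**
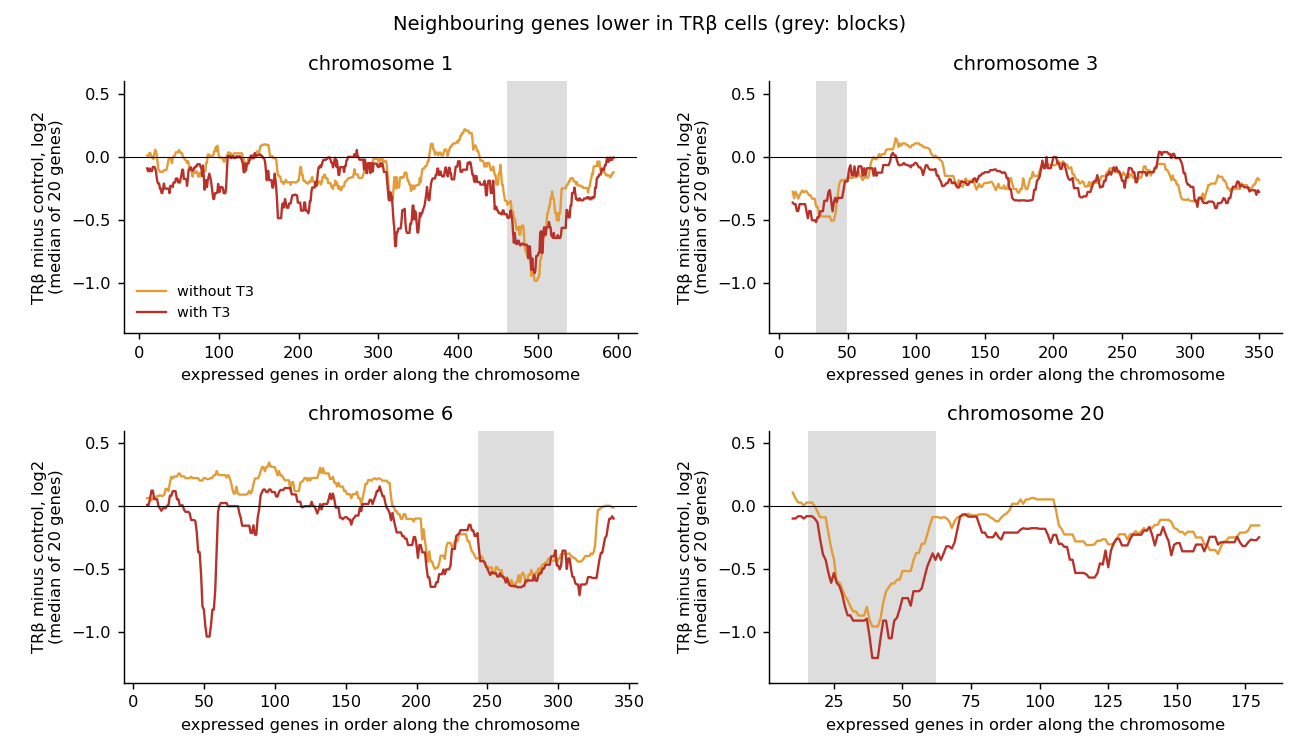
Median difference between TRβ and control cells (vertical axis, log2) in sliding windows of 20 neighbouring expressed genes, in their order along 4 chromosomes (horizontal axis, gene rank), without T3 (orange) and with T3 (red); grey marks the blocks. Both curves dip in the blocks of chromosomes 1 and 20, whose genes had medians of -0.62 and -0.61 without T3.

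In total 5080 probe sets differed between the untreated lines, 2956 higher and 2124 lower in TRβ cells. These represented 2380 of 22465 named genes, 940 higher and 1440 lower, so among the named genes more were lower. After quantile normalization the split of the probe sets was 2294 higher and 2567 lower, and after centring of array medians 1892 and 2497. The total fell to 2542 without untreated control replicate 2, 2581 without untreated control replicate 3, 2672 without TRβ replicate 1 and 2882 without TRβ replicate 3.

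With T3 in both lines, GLYATL2 was 297-fold higher in TRβ cells (8.21 ± 0.18, log2 ± SE), IFI6 90.5-fold and GABRQ 75.2-fold. NTN4, which encodes the secreted protein netrin-4, was 21.7-fold higher and PARP14, an interferon-responsive ADP-ribosyltransferase gene, was higher by 4.32 (log2). GFRA1 was 28.2-fold lower (-4.82 ± 0.12), BCL2 16.1-fold, DCPH1 15.4-fold, ABCA12 15-fold, IL20 14.7-fold, TFF1 11.8-fold and ESR1 9.6-fold (-3.26 ± 0.08). MKI67 was 2.85-fold lower and KLF9 1.52-fold higher. Of 20 interferon-stimulated genes, 18 were higher and none lower (20 higher adjusted over the list alone), with BST2 at 2.71 ± 0.10 and OAS3 at 1.95 ± 0.07. All 23 DNA replication genes and 22 of 23 mitosis genes were lower (23 and 23 adjusted over the list alone). The estrogen-induced list had 18 of 30 members lower and 3 higher (19 and 7 adjusted over the list alone), the luminal list 12 of 20 lower and 2 higher (13 and 3 adjusted over the list alone) and the cholesterol synthesis list 12 of 18 lower and 1 higher (13 and 1 adjusted over the list alone). KRT19, a luminal keratin gene, was lower by a log2 difference of -1.57 ± 0.09 and CXCL12, a chemokine gene, by -1.81 ± 0.12. Immediate-early genes were higher for 8 of 14 and lower for 1 (8 and 1 adjusted over the list alone), with EGR1 at 3.85 ± 0.15. Camera called these 7 lists at adjusted p-values of 4.71e-18, 7.17e-17, 1.25e-18, 1.43e-06, 2.37e-04, 2.07e-06 and 0.00253 (adjusted p = 0.0544, 0.104, 0.104, 0.104, 0.104, 0.104 and 0.123 with an estimated correlation).

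Mammary basal markers had 4 of 12 members higher and 1 lower (4 and 1 adjusted over the list alone), with EGFR at 1.10 ± 0.08 and CAV1, the caveolin-1 gene, at 1.75 ± 0.16. Genes of the epithelial-mesenchymal transition had 6 of 18 higher and 1 lower (6 and 1 adjusted over the list alone), with the fibronectin gene FN1 at 1.59 ± 0.09. Their adjusted p-values were 0.0274 and 0.0339 (adjusted p = 0.179 and 0.104 with an estimated correlation), and both calls ended with quantile normalization (0.0550 and 0.182), the basal call also without T3-treated control replicate 1 (0.0556). The T3-induced, oxidative phosphorylation and heat shock lists were called at 0.0367, 0.0247 and 0.0339 (adjusted p = 0.104, 0.347 and 0.347 with an estimated correlation), and all 3 calls ended with quantile normalization (0.0651, 0.663 and 0.428) and without dim probe sets (adjusted p = 0.185 each). Leaving out 1 array ended them too: T3-treated control replicate 2 (0.0560) or T3-treated TRβ replicate 1 (0.0696) for the T3-induced list, T3-treated TRβ replicate 3 (0.0932) for oxidative phosphorylation, and T3-treated control replicate 1 (0.0556) or 2 (0.0591) or T3-treated TRβ replicate 1 (0.0696) for heat shock.

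The 2 comparisons of the lines share no arrays. Their log2 differences correlated with Pearson's r of 0.411 and Spearman's rho of 0.306 across probe sets. Both called 1434 probe sets higher, against 316 expected from independent lists, and 1264 lower, against 177. With T3, 12824 probe sets differed, 7211 higher and 5613 lower in TRβ cells. These represented 5664 of 22465 named genes, 2254 higher and 3410 lower, so among the named genes more were lower. After quantile normalization 5149 probe sets were higher and 6062 lower, and after centring of array medians 3812 were higher and 7934 lower. Which direction held more probe sets thus depended on the scaling. Centring moved the median of all probe sets in this comparison by -0.11 (log2).

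**Figure D4:**
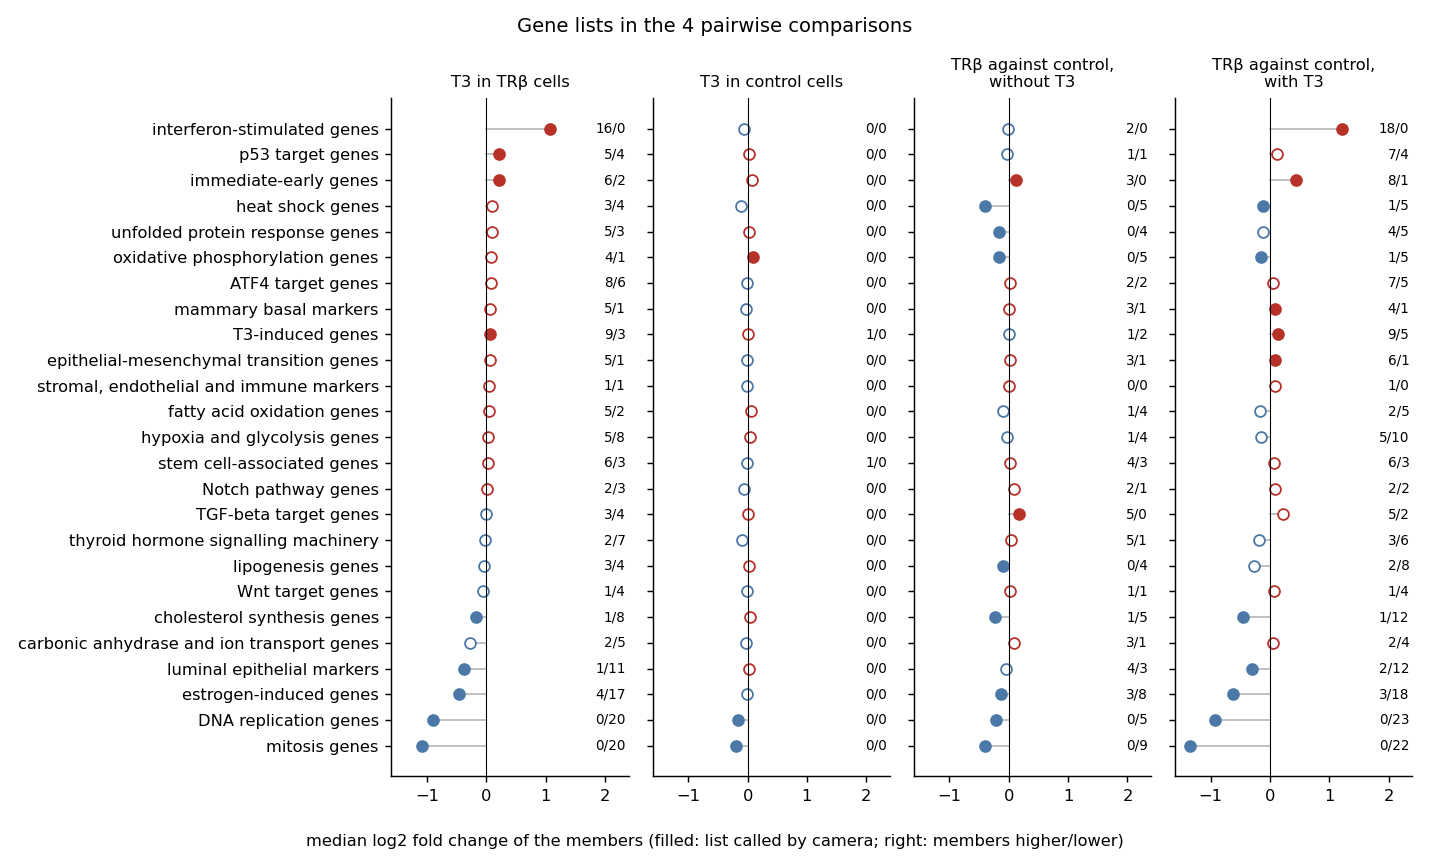
Median log2 fold change of the members of each of 25 gene lists (horizontal axis) in 4 comparisons; filled points were called by camera at the preset correlation, and the figures at the right give how many members were higher and lower. Interferon-stimulated genes lie at 1.08 for T3 in TRβ cells with 16 members higher, and mitosis genes at -1.08 with 20 lower.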

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

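The tests of the interferon-stimulated genes and of the dim probe sets were chosen after the result was seen, except leaving out each of the 6 arrays. The tests of the neighbouring genes were chosen after, except that of base composition. The other splits of the samples were chosen before.

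The results listed here differed between control and TRβ cells in their response to T3, by limma's test of the difference itself. The log2 response in TRβ cells minus that in control cells was 8.07 for GLYATL2, 6.84 for IFI6, 6.26 for GABRQ, 5.54 for ENPP2, 5.05 for UBD, 4.90 for ALDH1A3, 4.54 for HEG1, 4.49 for TNFSF10, 4.41 for IFIH1 and 4.18 for PARP14. It was -4.65 for TFF1, -4.34 for GFRA1, -3.65 for EFEMP1, -3.26 for BCL2, -3.19 for ERBB4, -3.13 for SLC7A2, -2.92 for SLC2A1, -2.89 for PRLR, -2.85 for RHOB and -2.81 for DCPH1. For ESR1 it was -2.63, for MKI67 -1.05, for KLF9 0.68 and for HR 0.39.

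Among the gene lists, the mean difference of the T3 responses was 1.55 for interferon-stimulated genes, -0.87 for mitosis genes, -0.69 for DNA replication genes, -0.63 for luminal epithelial markers, -0.57 for estrogen-induced genes and -0.23 for cholesterol synthesis genes. Camera called these lists at the preset correlation. With an estimated correlation it called only the interferon-stimulated genes (adjusted p = 0.0313), and the others had adjusted p = 0.144 to 0.284. In all, 4118 probe sets differed in their response. Of 100 splits of the 12 arrays, 10 gave as many, the real one included, and the highest other gave 6336, so chance cannot be excluded by this count. All 10 were among the 13 splits that kept the T3-treated TRβ arrays apart from the untreated TRβ arrays, and the other 87 gave 0, which points to the T3 response within TRβ cells as a structure that those splits kept.

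The interferon-stimulated genes averaged 6.39, 6.64 and 6.47 (log2) on the 3 T3-treated TRβ arrays and 4.90 to 5.02 on the other 9. RNA from immune, endothelial or stromal cells is argued against by the median T3 effect of 0.0467 (log2) over their 16 markers in TRβ cells, with an upper quartile of 0.0717, although CDH5, which rose, reached 7.42 and the next highest marker, CD68, 5.98. Quantile normalization left the list's mean T3 effect at 1.52. It moved all probe sets in this comparison by a median of only -0.00972 (log2), so it could hardly have lowered that mean. The intensity differences left between the arrays were thus too small to give the rise, and the authors' scaling was not tested beyond that. An exposure of the treated TRβ cultures other than the hormone cannot be told apart from a response to T3 through the added receptor: the list's mean T3 effect was -0.0425 in control cells, and the design has no other treatment of TRβ cells. A response to T3 that needs the added receptor may explain the pattern and was not tested separately. Another difference between the lines that changes the T3 response would give the same values.

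The neighbouring genes on chromosomes 1 and 20 that were lower in untreated TRβ cells had a median difference of -0.70 (log2) between the T3-treated lines, on arrays that had no part in finding them. The blocks on chromosomes 3 and 6, which the tests did not cover, were at -0.36 and -0.55 there. Unequal copy number was taken to need -0.5 on chromosomes 1 and 20. The chromosome 3 block was short of that bound already in the comparison that found it (-0.48), so the bound cannot decide on this block. The pattern was found without added T3. The median effect of added T3 on these genes in TRβ cells was -0.0533 over members that moved both ways (interquartile range 0.553). By chromosome it was -0.00333 (chromosome 1) and -0.12 (chromosome 20), so added T3 did not shift these genes together as a set. Regulation by any hormone in the serum was not tested and cannot be told apart. A base composition trend cannot be told apart. The lowest window on the AT-rich chromosomes 4, 13 and 18 was at -0.39, too near the bound of -0.4 set for this test. Unequal DNA copy number between the lines may explain the pattern and has the values it needs, but no DNA was measured, and repression by the receptor that does not depend on T3 would give the same values and was not tested.

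Probe sets with a mean at or below the median of 4.78 were called higher 1896 times and lower 149 times (92.7% higher) between the T3-treated lines, against 5315 and 5464 (49.3% higher) among brighter ones. A single array among the 6 is argued against, since the share remained at 89.8% or more when each was left out. After quantile normalization 652 were called higher and 532 lower (55.1% higher), so most of the excess depended on the scaling. The excess was not particular to the T3-treated lines. Calls of these dim probe sets were 265 higher and 60 lower between the untreated lines. They were 633 and 334 for T3 in TRβ cells, and 291 and 59 for the difference of responses. After quantile normalization 57.6%, 58.0% and 65.6% of the calls in these 3 comparisons were higher. T3 in control cells called 1 of them. Unequal intensity distributions left by the normalization cannot be told apart from a difference between the cells. No biological explanation was tested.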

How the results depend on the processing

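Removal of alternate haplotype probe sets was chosen after the data were seen; the other tests were chosen before. Of 482 gene results, 458 of them called, none turned direction under any alternative while called. eBayes without trend, robust eBayes and haplotype removal left all those that they covered on their side of the threshold. Calls ended for 21 results with centring, 18 with only the 2 groups compared, 9 with the replicate number as a block, 8 with quantile normalization and 1 with array weights, and 291 times over the 12 fits that each left out 1 array. Of 40 called lists, 39 ended with an estimated correlation, 12 without dim probe sets, 11 with quantile normalization, 3 with fry and 1 with the block, and calls ended 19 times with 1 array left out. The labels do not pair samples by replicate number, and not every same-number pair deviated together. Deviations from the group means correlated at -0.13 to 0.245 in 18 such pairs (median 0.056, 6 over 0.1) and at a median of -0.05 in 36 other pairs (2 over 0.1). As a hint of shared handling, 8 of 12 arrays correlated best with their own number, and all 3 pairs between the T3-treated lines were over 0.1 (0.114, 0.164 and 0.104). The block gave 26 probe sets for T3 in control cells and 12568 for TRβ against control with T3. With it, the adjusted p was 0.0767 for the difference of KLF9 responses, 0.0512 for the T3-induced list with T3 in TRβ cells and 0.0175 for THRSP between the T3-treated lines.

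In the order T3 in TRβ cells, T3 in control cells, TRβ against control without T3, with T3, and difference of responses, the counts were 1980, 18, 595, 2002 and 1314 with a 2-fold minimum. They were 5723, 19, 2005, 7266 and 2014 at an adjusted p under 0.01, and 2023, 25, 640, 2032 and 1680 at an unadjusted p under 0.05 with a 2-fold minimum. An estimated correlation called 0, 0, 0, 0 and 1 lists, and fry 19, 0, 16, 24 and 17, against 9, 3, 10, 12 and 6. With 1 probe set per gene, and so fewer tests, 6100 passed for T3 in TRβ cells, 81 for T3 in control cells and 7092 for TRβ against control with T3. With only the 2 groups compared, and so fewer arrays, T3 in TRβ cells gave 6109, and array weights gave 89 for T3 in control cells. Without dim probe sets the T3 responses of the 2 lines correlated at 0.384, and 5 lists were called for TRβ against control without T3.

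Leaving out 1 array gave 11 to 67 probe sets for T3 in control cells, lowest without T3-treated control replicate 2 and highest without T3-treated TRβ replicate 1. TRβ against control without T3 ranged from 2542 to 6064, and the correlation of the T3 responses from 0.202 without untreated control replicate 1 to 0.378 without untreated control replicate 2. The cause of changes not explained by fewer tests or arrays was not tested. No background level was given, so what depends on signal over background was not measured.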

Other observations

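The gene groups in the next 2 paragraphs and the test of genes raised by T3 in control cells were chosen after the result was seen; the splits of the samples were chosen before.

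Of 29 replication-dependent histone genes, 24 fell and none rose with T3 in TRβ cells by limma's test, with a median log2 change of -1.25 (-1.15 after quantile normalization and -1.27 after centring of array medians). H2BC10 was at -2.46, H2BC17 at -1.86 and H1-4 at -1.83. In control cells the median was -0.02, with the sign turned by centring (0.02), and 22 of these genes passed the test of the difference between the responses. Of 15 antigen processing genes, 13 rose and none fell in TRβ cells, with a median of 0.96. TAP1, a peptide transporter gene, rose by 3.60, the peptidase gene ERAP1 by 2.99 and B2M, the light chain of MHC class I, by 2.24. In the test of the difference, 13 of the 15 had a larger response in TRβ cells.

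All 9 measured metallothionein genes were lower in TRβ than in control cells, both without T3 (median -0.59) and with T3 (median -0.90). Without T3, MT2A was at -1.65, MT1F at -1.16 and MT1X at -0.87. MT1G and MT1M had mean signals of 4.64 and 4.74 (log2), under the median of 4.78 over the means of all probe sets. Of 42 probe sets named for the MIR548 microRNA family, 26 were higher in TRβ cells without T3 and none lower, with a median of 0.87, and 25 were higher with T3, with a median of 0.84. These probe sets were taken to read precursor or host transcripts, and whether each reads a transcript of its own was not tested. MIR548AI and MIR548AJ2 had almost the same mean signal (16.334 and 16.333, log2) and difference without T3 (1.33 and 1.32). The MIR548 probe sets may therefore not be separate measurements. Whether those of the histone and metallothionein genes are separate measurements was not tested either. After quantile normalization and after centring of array medians, the counts of histone, antigen processing and metallothionein genes given here were the same, and those of the MIR548 probe sets were 25 without T3 and 24 with T3. The named members kept their direction under both.

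A hypothesis was that the added receptor, without added T3, represses genes that T3 raises. The cells grew in medium with fetal bovine serum, and hormone in it was not measured. Of the 28 genes that T3 raised in control cells, 18 were lower in untreated TRβ than in untreated control cells, 10 of them called, and 5 were called higher; the mean was -0.35 and the median -0.12. Camera gave p = 0.00376 at the preset correlation and p = 0.116 with an estimated correlation, so such repression may be present but cannot be told apart from the correlation between the genes. These genes were chosen partly for low values on the untreated control arrays, which works against lower values in TRβ cells.

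Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, reached the real count in each. The real count and the highest other were 9348 and 0 for T3 in TRβ cells, 40 and 1 for T3 in control cells, 5080 and 0 for TRβ against control without T3, and 12824 and 4 with T3.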
